A study of Homo sapiens with 6 samples.

How the data were processed

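Ribosome footprints were measured in HEK293T cells, a human embryonic kidney line, transfected with a vector for FLAG-tagged DHX29. DHX29 is a DExH-box RNA helicase known to bind the small ribosomal subunit. Per the labels' protocols, the cells were crosslinked with DSP, a protein crosslinker, and the lysates were digested with RNase I. A part of the lysate was kept as input. The rest was spun through a sucrose cushion, cleared on beads and precipitated with an anti-FLAG antibody. Footprint libraries were made by Thor-Ribo-Seq, a low-input ribosome profiling method. There were 3 Input libraries and 3 DHX29-IP libraries, grouped by their titles. A control precipitation from cells without the tag was not analysed here.

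The deposited values are whole-number counts per transcript, 1 table per library, with no replicates pooled. Per the submitters' processing notes, fastp 0.21.0, STAR 2.7.0a and the hg38 genome build were used; their settings, the annotation release, the counting step and the treatment of duplicate or multiply mapped reads are not given in the sources used here. The tables listed 227264 Ensembl transcripts, of which 126981 had no length and no count in any library. The other 100283 carried a whole number that is not explained in the deposited tables. It ran from -9 to 35982, and all 380 transcripts at 0 or below had no count. It is called the listed length here and was taken as the number of coding codons in which reads were counted; its unit is not stated in the file or the labels.

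Overlapping transcripts often had equal counts, so a read appears to be counted for every transcript that contains it. The deposited totals therefore exceed the number of reads and the true depth is unknown. Of 94478 transcripts with a count, rows with identical counts in all 6 libraries were merged into 56209 rows, keeping the first transcript and its length. Among 4367 sets of identical rows with a total of at least 60, 11 spanned more than 200 coding transcripts of the table, so some reads were counted at distant places, and such rows are uncertain. Counts of calls refer to transcript rows, not genes. CPM are counts scaled to a common library total.

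The deposited tables do not pair transcripts with gene names, and 0 transcript IDs matched the reference table of gene names that was used. No row was therefore assigned to DHX29 or to any other gene, and a row given by ID may belong to any gene, the transfected one included. The gene lists fixed beforehand and the GC content at the wobble position of codons, both named in the plan, were not analysed here. The plan's tests per gene were run per transcript row, and listed length took the place of wobble-position GC in the value per library. The rule for named items (largest changes past the threshold, a mean of at least 10 CPM, all IP libraries on one side of all Input libraries) was limited for the same reason to 2 IDs in each direction, 1 per stretch of the table, a limit set after values were seen. Rows described by their listed length alone were also chosen after their values were seen. Of the called rows, 41 higher and 10 lower ones met that rule. Called rows within 40 coding transcripts of each other were counted as one stretch.

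The main test was edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors, R 4.3.3) on the counts with group as the only term. Rows were filtered with filterByExpr (minimum count 10), which left 29097 rows. The Benjamini-Hochberg threshold was 0.05. Standard errors were derived from the F statistic. Median counts per tested row ranged from 15 to 40 per library, and the common biological coefficient of variation was 0.136. The procedure was tested on simulated data drawn for the 29097 rows of this comparison. It recovered 6.67% of 60 rows changed 1.5-fold, 35.9% of 64 changed 2-fold and 96.8% of 62 changed 4-fold, and 7.45% of its calls were false. The simulated rows were independent, with the same dispersion in both groups and no rows raised in a single library. The real rows share reads and were noisier in the IP, so these rates may not hold for them. A simulated slope of 0.1 on log2 length was found as 0.0998.

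The relation to listed length was measured by the Spearman correlation and a linear slope across rows, by deciles, and by the CPM-weighted mean length per library with an exact permutation test. Standard errors of decile medians came from 200 bootstrap draws of groups of near-identical rows and do not cover the spread between libraries. Rows were called near-identical when the summed squared difference over the sum of counts was under 1 within 30 rows; 20654 groups resulted. Spikes were counted after thinning every library to 648803 counts, 1 row per group, as rows with at least 20 counts and at least 5 times both other libraries of their group. Between libraries, noise was the median over rows of the squared difference over the sum of the thinned counts, relative to its value under counting noise alone.

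Alternatives fixed before the data were examined were DESeq2 1.42.0, other scalings, other filters, a minimum fold change, the replicate number as a block, and each library left out. Rows unmerged or merged further, a length correction and limma 3.58.1 (voom with sample weights) were added after seeing the data. The merging of identical rows, the stretch distance, the definition of spikes and the use of listed length by decile, per library and for called rows were also set after seeing the data. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries.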

Results

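Ribosome footprints from the anti-FLAG precipitation were compared with footprints of the input lysate in HEK293T cells transfected for FLAG-tagged DHX29, with 3 libraries in each group. No control precipitation was analysed, so the share of IP footprints that came down through DHX29 was not measured. Deposited totals, in which overlapping transcripts share reads, were 3169648, 2446078 and 3427786 counts in Input replicates 1 to 3. They were 1585103, 1899273 and 1257141 counts in DHX29-IP replicates 1 to 3. All IP libraries were thus smaller than all Input libraries. Between 75787 and 82942 transcripts had a count in each library. The 10 highest tested rows held 1.42% to 1.51% of the counts in Input and 1.88% to 2.15% in the IP. In the IP they included 2 near-identical rows, ENST00000251636.10 and its neighbour. These had means of 4519 and 4493 CPM in the IP against 674 and 671 CPM in Input, so the higher IP share is not a general concentration of counts.

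Footprint levels were close between libraries within and between groups. Across the 29097 tested rows, Pearson correlations of log2 CPM were 0.951, 0.952 and 0.959 between Input libraries. They were 0.857, 0.889 and 0.892 between IP libraries and 0.891 to 0.927 between an IP and an Input library. Each IP library correlated more highly with each Input library than with either other IP library. These correlations were not taken at equal totals, so the greater counting noise of the smaller IP libraries may account for part of this. After thinning to one total, the median squared difference between replicates was 1.17 to 1.24 times that of counting noise in Input and 1.41 to 1.80 times in the IP.

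The first question was which transcripts are over- or underrepresented among the footprints of the DHX29-IP libraries. In the IP, 44 rows were higher and 12 were lower than in Input, together 0.192% of those tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The higher rows lay in 27 stretches of the table and the lower rows in 8. Fold changes of the higher rows ranged from 0.60 to 2.74 on the log2 scale with a median of 1.32, and 31 of them exceeded 2-fold. The lower rows ranged from -0.46 to -1.89 with a median of -0.93, and 5 of them exceeded 2-fold. In all 56 called rows the 3 IP libraries did not overlap the 3 Input libraries. Among all tested rows 13.9% did not overlap, where chance gives 10%. The median log2 fold change of all rows was 0.0011.

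**Figure D1:**
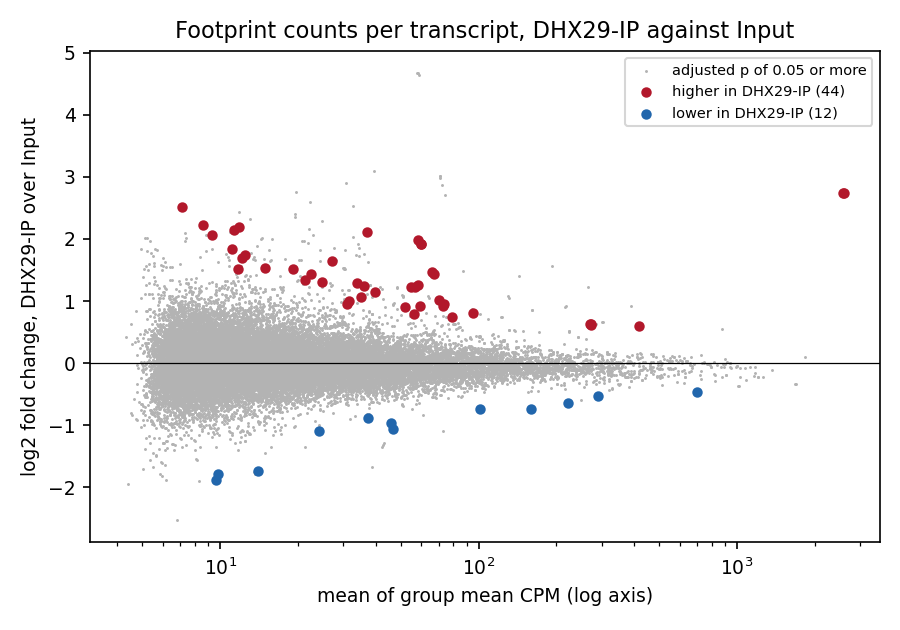
Log2 fold change of DHX29-IP over Input against mean CPM (log axis) for the 29097 tested rows; red points are the 44 higher and blue points the 12 lower rows, grey points did not pass. The red point at 2597 CPM is ENST00000251636.10.

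The largest log2 fold change of the called rows was that of ENST00000251636.10, with a listed length of 1360. It had 674 ± 105 CPM in Input and 4519 ± 613 CPM in the IP (SD, n = 3), a 6.70-fold rise (log2 fold change 2.74, SE 0.13, edgeR adjusted p = 4.1e-07). Its counts were 1841, 1050 and 1653 in the Input libraries and 6060, 5767 and 3818 in the IP libraries. It ranked 62nd of the tested rows in Input and had the highest mean in the IP. Transcripts were not matched to genes, so whether this row belongs to the transfected gene was not tested. A neighbouring row of listed length 1361 had nearly the same counts and is not independent of it. The rise passed the threshold in all 17 alternatives in which it was evaluated, with edgeR, DESeq2 or limma adjusted p of at most 0.020.

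The other higher rows were less abundant. ENST00000299798.16, with a listed length of 887, had 4.47 ± 1.22 CPM in Input and 19.2 ± 11.1 CPM in the IP (SD, n = 3; log2 fold change 2.19, SE 0.42, edgeR adjusted p = 0.035). Its counts were 11, 10 and 8 in Input and 27, 39 and 6 in the IP. This call was lost without Input replicate 1 (edgeR adjusted p = 0.28), Input replicate 2 (0.147), Input replicate 3 (0.34) or DHX29-IP replicate 1 (0.22). It was lost in 7 of 16 alternatives in all, with edgeR, DESeq2 or limma adjusted p from 3.7e-05 to 0.34. In a stretch of 4 higher rows, fold changes ranged from 3.76 to 4.34, and its most abundant row, of listed length 640, rose 3.76-fold, from 25.5 ± 3.80 to 94.4 ± 25.4 CPM. In a stretch of 2 higher rows, which rose 2.69-fold and 2.76-fold, the more abundant row, of listed length 704, went from 36.1 ± 1.98 to 97.8 ± 22.2 CPM. A row of listed length 307 rose 2.38-fold, from 34.6 ± 6.40 to 82.1 ± 5.59 CPM. Smaller changes passed in rows of several lengths. A row of listed length 179 rose 1.68-fold, from 58.8 ± 7.38 to 99.3 ± 16.3 CPM, and one of listed length 449 rose 1.76-fold. The smallest were in abundant, long rows. A row of listed length 1951 rose 1.52-fold, from 333 ± 23.7 to 504 ± 42.3 CPM, and one of listed length 1967 rose 1.54-fold, from 215 ± 6.57 to 331 ± 13.6 CPM.

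The lower rows were mostly short. ENST00000217162.5, with a listed length of 474, had 21.6 ± 6.42 CPM in Input and 6.46 ± 1.40 CPM in the IP (SD, n = 3; log2 fold change -1.73, SE 0.33, edgeR adjusted p = 0.017). It lost the call without Input replicate 2 (edgeR adjusted p = 0.151), Input replicate 3 (0.080) or DHX29-IP replicate 1 (0.052). It was lost in 5 of 17 alternatives in all, among them DESeq2 (adjusted p = 0.108), with adjusted p from 0.0039 to 0.151. ENST00000540874.5, with a listed length of 47, had 32.9 ± 0.82 CPM in Input and 15.5 ± 2.65 CPM in the IP (log2 fold change -1.10, SE 0.22, edgeR adjusted p = 0.028). It lost the call without Input replicate 1 (edgeR adjusted p = 0.138), 2 (0.130) or 3 (0.24). It was lost in 7 of 17 alternatives in all, with adjusted p from 0.013 to 0.29. Among them were DESeq2 (adjusted p = 0.29) and the replicate block (edgeR adjusted p = 0.068). The most abundant lower row, of listed length 120, had 816 ± 64.0 CPM in Input and 591 ± 68.4 CPM in the IP. A row of listed length 119 went from 273 ± 31.8 to 172 ± 31.0 CPM, and one of listed length 41 from 201 ± 1.80 to 120 ± 30.3 CPM. The lower row with the shortest listed length, 34, went from 63.2 ± 5.25 to 29.8 ± 3.41 CPM.

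**Figure D2:**
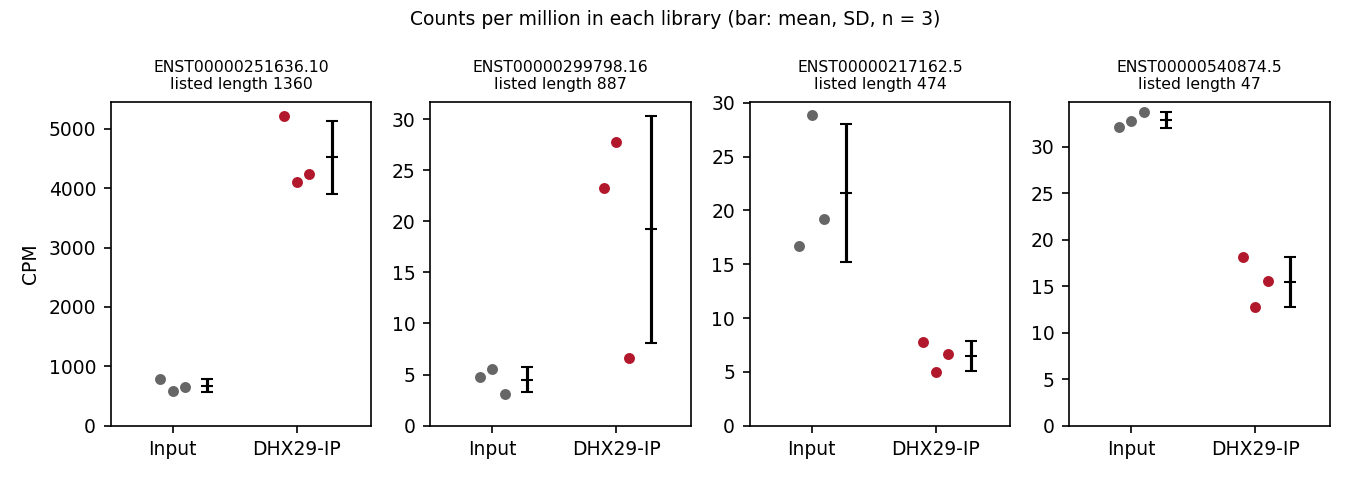
CPM in each library for the 4 transcripts given by ID, Input in grey and DHX29-IP in red, with mean and SD (n = 3) beside the points. For ENST00000251636.10 the 3 IP libraries lie between 4099 and 5223 CPM and the 3 Input libraries between 583 and 790.

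The number of calls depended on single libraries. It was 28 higher and 6 lower without Input replicate 1, 41 and 4 without Input replicate 2, and 15 and 1 without Input replicate 3. It was 51 and 6 without DHX29-IP replicate 1, 269 and 146 without DHX29-IP replicate 2, and 80 and 21 without DHX29-IP replicate 3. The filter was applied anew each time, so these counts are not over the same rows. Without Input replicates 1, 2 and 3, 28892, 28655 and 28762 rows were tested. Without DHX29-IP replicates 1, 2 and 3, 32833, 32810 and 32778 rows were tested. Of the 44 higher rows, 27, 34 and 14 were called again without Input replicates 1, 2 and 3, and 28, 42 and 40 without DHX29-IP replicates 1, 2 and 3. Of the 12 lower rows, these numbers were 3, 3 and 1 for Input and 6, 11 and 10 for the IP. DESeq2 called 30 of the 44 and 6 of the 12. At an unadjusted p under 0.05 edgeR gave 2263 rows, or 7.78% of those tested. With a correction for listed length the split of higher and lower calls was 35 and 3 (92.1% higher) in place of 44 and 12 (78.6% higher).

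The difference between IP and Input was then set against the listed length of the coding region. The plan had set a relation with coding length across genes, using reference coding sequences, beside that with codon GC content. The listed length across transcript rows stood in for it here. Deciles of listed length, the values per library and the lengths of called rows were added after seeing the data. Rows with longer listed lengths tended to be higher in the IP and those with shorter ones lower. Overlapping transcripts of different lengths are separate rows that can share reads. A short row is therefore not necessarily a short translated mRNA. The median log2 fold change rose through all 10 length deciles, from -0.13 (bootstrap SE 0.0075, listed lengths 4 to 110) to 0.16 (bootstrap SE 0.010, listed lengths 1123 to 35982). In the shortest decile 34.6% of rows had a positive fold change, against 73.2% in the longest. The longest decile held 17 of the 44 higher calls and 0 lower calls, and the shortest held 1 higher and 7 lower calls. With 1 row per near-identical group, the higher calls had a median listed length of 756 (n = 34) against 303 for the remaining rows. The lower calls had a median of 95 (n = 11) against 304. The permutation tests did not compare these medians. They set the mean log2 length of the calls against that of equally many rows drawn from all groups. The two-sided permutation p was 1e-05 for the higher calls, the smallest that 100000 resamples can give. It was 2e-05 for the lower calls. Both adjusted p over these 2 permutation tests were 2e-05 (Benjamini-Hochberg). These tests treated groups as independent, although the 34 higher groups lay in 27 stretches and the 11 lower groups in 8. They do not cover the spread between libraries. The calls rest on the same fold changes as the deciles, so their lengths are not separate evidence for the trend.

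Across the 29097 rows, which are not independent replicates, log2 fold change and listed length had a Spearman correlation of 0.27 and a Pearson's r of 0.27 with log2 length. The slope was 0.076 log2 units per doubling of length. The Spearman correlation was 0.25, 0.25, 0.30 and 0.34 from the lowest to the highest quartile of mean CPM. It was -0.087 with the mean level and -0.25 with CPM per listed codon, a ratio that contains the length. Together with 2 partial correlations, 5 such relations were computed over all rows.

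Set against the mean of the 3 Input libraries, DHX29-IP replicates 1, 2 and 3 had slopes of 0.059, 0.033 and 0.125. These slopes share 1 Input mean, so their equal sign is not independent evidence. Each Input library set against the other two gave -0.029, 0.018 and 0.011, and the slope of DHX29-IP replicate 2 was close in size to the largest of these. The CPM-weighted mean listed length was 645 ± 43.9 in the IP and 599 ± 9.48 in Input (SD, n = 3). The 46.0 difference had p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 libraries can give. Without DHX29-IP replicate 3, the Spearman correlation was 0.152, the slope 0.049 and the difference in weighted length 21.8.

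**Figure D3:**
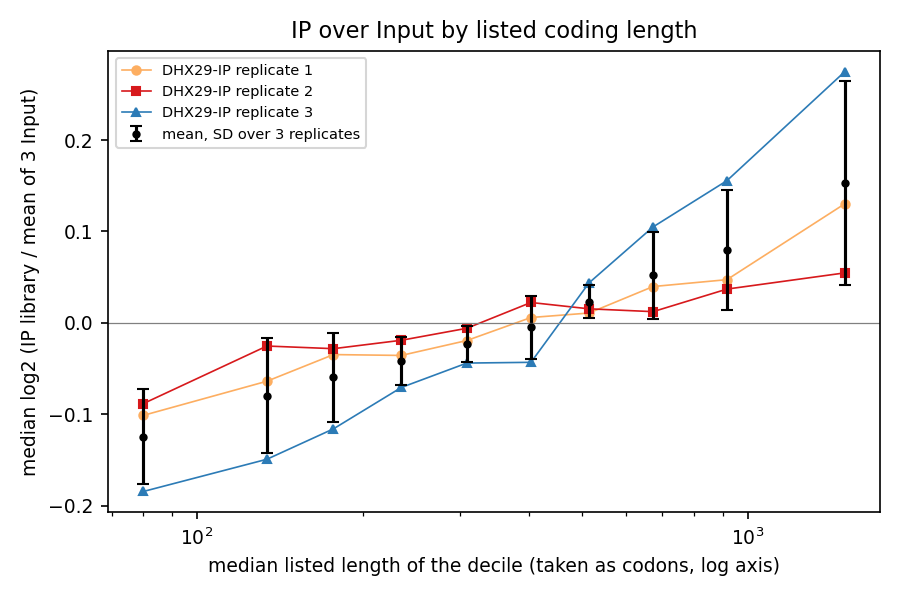
Median log2 ratio of each DHX29-IP library to the mean of the 3 Input libraries, by decile of listed length (median length of the decile on a log axis); black points and bars are mean and SD over the 3 IP libraries. All 3 IP libraries are below 0 in the shortest decile and above 0 in the longest, from 0.055 in replicate 2 to 0.27 in replicate 3.

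Some rows were high in a single library. With all libraries thinned to one total, 61 rows in DHX29-IP replicate 3 were at least 5 times above both other IP libraries. The other libraries had 4, 2 and 2 such rows in Input replicates 1 to 3, and 3 and 1 in DHX29-IP replicates 1 and 2. The spiked rows held 0.82% of the thinned counts of DHX29-IP replicate 3, and the largest was 26.1 times above the next IP library. Of the 61 rows, 0 were also spiked in an Input library.

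**Figure D4:**
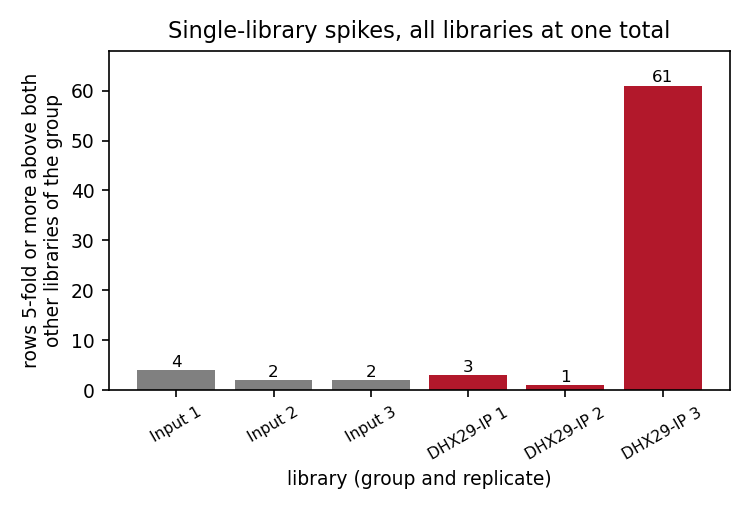
Number of rows in each library with at least 20 counts and at least 5 times both other libraries of its group, after thinning to 648803 counts per library (1 row per near-identical group, 20654 rows). DHX29-IP replicate 3 has 61 and the other libraries have 1 to 4.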

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

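Of 18 alternative settings, ENST00000251636.10 was evaluated in 17 (not with the minimum fold change) and passed in all of them, between 2.62 and 2.88 on the log2 scale. The other transcripts given by ID kept their sign throughout but lost the threshold in 7 of 16 settings (ENST00000299798.16), 5 of 17 (ENST00000217162.5) and 7 of 17 (ENST00000540874.5). Leaving out 1 library moved the higher calls between 15 (without Input replicate 3) and 269 (without DHX29-IP replicate 2), the lower calls between 1 and 146 (the same libraries), and the rank correlation with length between 0.152 and 0.277; the causes were not tested. DESeq2 gave 7 lower calls. A minimum fold change of 1.5 left 8 higher and 0 lower calls (edgeR's treat test; 288 and 128 rows at an unadjusted p under 0.05), since it tests a stricter hypothesis. The length correction gave 35 higher and 3 lower calls and a correlation of 0.030, which it removes by construction. With the replicate block, 41 higher and 10 lower rows were called, 36 and 8 of them also without it. The numbers were not shown to pair the libraries: deviations from the group means correlated at 0.063, 0.0042 and 0.014 for equal numbers (7621 rows), and by these correlations 0 of 3 IP libraries lay closest to the Input library of its own number. By the correlation of log2 CPM all 3 IP libraries lay closest to Input replicate 3, so 1 of 3 matched its own number. Input replicate 3 had the largest total, which may account for this, so it says little on pairing. For DHX29-IP replicate 2 the margin was small (0.9213 against 0.9210 for Input replicate 1). Other scalings, filters and row merging gave 40 to 54 higher calls except 37 with near-identical rows merged and 59 with limma-voom, and 10 to 17 lower calls. With these depths and 3 libraries in each group, simulated 2-fold changes were recovered in 35.9% of cases; the part of depth in this was not tested. Settings that need gene names or coding sequences (gene sums, removal of DHX29 and mitochondrial genes, base composition, gene lists) and the pseudocount, which applies to normalized values, were not run. The 4 settings on rows, length and limma-voom were chosen after seeing the data.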

Other observations

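Across the 29097 rows, which are not independent replicates, the Spearman correlation between log2 fold change and mean CPM was -0.087, and -0.128 with the listed length held fixed. With mean CPM held fixed, the correlation with length was 0.28. The correlation of -0.25 with mean CPM per listed codon has the length as its denominator, so it is not separate from the relation with length. Transcripts were not matched to genes, so whether any called row belongs to the transfected gene was not tested.

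The relations with footprints per codon, the partial correlations, the definition of spikes, the comparison of spiked rows in Input replicates 1 and 2, and the use of the spread between libraries in the test of missing codons were chosen after seeing the data. Both patterns weighed next had been noticed in the data before their tests were set.

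The rise of fold changes with listed length was first set against a fixed number of codons missing from the IP reads: a window of 5.5 codons, fitted on listed lengths above 40 and under 300, predicted a rise of 0.021 from the fifth to the tenth decile. The rises in the IP libraries were 0.150, 0.061 and 0.32, on average 2.056 SE over libraries above the prediction, and although a bound of 2 SE had been set beforehand, it was too loose for 3 libraries that share 1 Input mean, so this explanation stays open. Lower depth of the IP libraries is argued against by thinning, which left the slope at 1.085 times the unthinned one on the same 20383 rows. Without DHX29-IP replicate 3, which holds most of the single-library spikes, 0.653 of the slope was left, so a part of the trend may belong to that library. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave a correlation as large (the real one, 0.27, against at most 0.21 in the others), too few splits for a share under 0.05; a property of DHX29-bound ribosomes and an effect of the cushion, clearing and antibody steps, which only the IP libraries went through, both stay open and untested.

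The 61 spikes of DHX29-IP replicate 3 were 15.25 times as many as in the next library at equal totals, which argues against its lower depth. A uniformly smaller number of sampled molecules would raise the noise of most rows. The median noise factor of its pairs was 0.946 times that of DHX29-IP replicates 1 and 2. This ratio is a weak test, because DHX29-IP replicate 2 is in the reference pair and also in 1 of the pairs compared. Against DHX29-IP replicate 1, the factor was 1.41 for replicate 3 and 1.70 for replicate 2, which had 1 spike. Median noise thus did not set replicate 3 apart from replicate 2. All IP pairs lay above the Input pairs (1.17 to 1.24), so fewer sampled molecules than in Input stay possible. A difference already in the lysate would need the same rows to be high in an Input library, but their median ratio to the other Input libraries was 1.038 in Input replicate 3 (quartiles 0.859 to 1.29, 61 rows), 0.877 in replicate 1 and 1.05 in replicate 2, which argues against it for these 3 lysates. Uneven amplification of few molecules in that library stays a candidate explanation that was not tested, since the tables hold no read positions. No biological explanation was tested, because the design gives these replicates no difference.

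For the calls between IP and Input, 1 of the 10 splits gave as many rows, the real one with 56, and the highest other split gave 4; 10 splits are too few for a share under 0.05. Without DHX29-IP replicate 2 there were 269 higher and 146 lower calls, and limma gave that library a sample weight of 0.613, against 1.04 to 1.16 in the others.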
